A study of Mus musculus with 2 samples.

How the data were processed

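Small RNA was sequenced from GC-1 cells, an immortalised mouse spermatogonia line, in 2 libraries. One came from cells kept at 0 nM MC-LR (control) and one from cells exposed to 500 nM MC-LR for 24 h. MC-LR is microcystin-LR, a cyclic peptide toxin of cyanobacteria that inhibits serine/threonine protein phosphatases. Per the labels' protocols, total RNA was extracted with TRIzol and libraries followed the sequencer maker's usual preparation.

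The deposited values are counts. One table per library lists reads per annotated mouse piRNA, for 39986 piRNAs with a 0 where no read was assigned, and a second table lists reads per distinct sequence (tag) assigned to a piRNA, with the lengths of the tag and of the piRNA. Build mm8 is named in the submitters' processing notes. The aligner, the trimming and mismatch rules and the piRNA collection are not given in the sources used here. The deposited counts are whole numbers and were taken as not normalised. In both libraries the tag reads were checked to sum to the count of each piRNA, with 0 disagreements. All 220 control tags and all 230 MC-LR tags lie inside their piRNA without a mismatch and are 0 to 3 nt shorter than it. Forms that were longer, mismatched or more than 3 nt shorter were therefore not measured. Of these tags, 5 in the control and 6 in the MC-LR library, with 12 reads in each, also fit another detected piRNA and stand under 1 of them only.

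The control library holds 244066 piRNA reads and the MC-LR library 359871. A single read is worth 4.10 counts per 1000000 piRNA reads (CPM) in the control and 2.78 CPM in the MC-LR library, and the floor of 3 reads used for a piRNA without reads is worth 12.3 and 8.34 CPM. With 1 library per group there was no test of the conditions and no replicate check, and no p-value across piRNAs is given. Each piRNA was compared by the ratio of its CPM, MC-LR over control, scaled to the total of piRNA reads. The 95% interval of the ratio is the exact (Clopper-Pearson) interval of the share of a piRNA's reads that came from the MC-LR library. Intervals of shares are exact binomial intervals, those of ratios of ratios rest on the log odds ratio, and those of differences between shares on the 2 single shares. PCR reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only and compare these 2 libraries, not the conditions.

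A piRNA was counted as higher with at least 10 reads in a library, a CPM ratio of at least 2 and an interval that excludes 1, and as lower with a ratio of at most 0.5 under the same conditions. The piRNAs named are the 10 most abundant by mean CPM and, in each direction, up to 10 with the largest ratio among those that met the rule; other piRNAs are said to have been chosen after their values were seen. Alternatives were edgeR TMM factors, DESeq2 size factors, the total without the 10 most abundant piRNAs, the total without the most abundant piRNA, other read minimums and folds, an exact binomial test with Benjamini-Hochberg adjustment in place of the interval, and sums over piRNAs that share 18 nt. The rule was tested on simulated data: Poisson counts of the 90 detected piRNAs were drawn 100 times from the means and depths of these libraries. It recovered 99.4% of tested piRNAs with a simulated fold of 4, 88.7% at 2.5, 85.0% at 0.4 and 98.3% at 0.25, and called 1.85% of unchanged ones. That simulation holds counting error alone, with no variation between cultures. The most abundant piRNA was never changed in it. A shift of all other ratios through the total of piRNA reads is thus not covered by the 1.85%.

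The lists fixed beforehand were fragments of structural RNAs (36 sequences of tRNA, rRNA, snRNA, Y RNA and 7SK), piRNAs of 26 to 28 nt, piRNAs of 29 to 31 nt, piRNAs with and without a first-base U, piRNAs with A at position 10, and piRNAs with 1 or with more than 10 matches. A list's median log2 ratio was placed among 10000 random lists of equal size matched on mean expression, as a description of these libraries. The detected piRNAs were matched exactly, on both strands, to the transcripts of GENCODE M21 (GRCm38), which is not the build of the authors. Coordinates are from that match, counted from 1, and cover exons only: a genome was not used here, so introns and intergenic sequence were not searched and the number of matches is that of exonic loci. The RNA classes built from this match (miRNA hairpin, snoRNA, and so on) and their lists were chosen after the files were seen. A sequence with several matches was put in the first class that applied: the fixed structural RNAs, then miRNA hairpin, snoRNA, snRNA, the ribosomal RNA locus, repeated and other exons. Of the 26 hairpin piRNAs, 7 match more than 10 exonic loci and stand there by this order, with 30 reads in each library. mmu_piR_035888, mmu_piR_028252 and mmu_piR_010309 also match a snoRNA or scaRNA entry at the same place, and stand under hairpins by this order too. The software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.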

Results

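The piRNA profiles of GC-1 spermatogonia were compared between 1 library of untreated cells and 1 library of cells exposed to 500 nM MC-LR for 24 h. The question set by the design was which piRNAs differ in abundance after exposure to the toxin. The control library held 244066 reads assigned to piRNAs and the MC-LR library 359871. Of the 39986 annotated piRNAs, 76 had a read in the control and 77 in the MC-LR library, or 72.2 at the depth of the control. Both libraries shared 63 piRNAs, with 13 seen in the control alone and 14 in the MC-LR library alone. Of these 27 piRNAs, 26 had fewer than 10 reads, below the minimum set for a comparison. At least 10 reads in a library were found for 43 piRNAs.

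A single sequence made up most of both profiles. mmu_piR_000691 (CTGGGAATACCGGGTGCTGTAGGCTT, 26 nt) lies within 5S ribosomal RNA, a structural part of the large ribosomal subunit. It took 213759 reads or 87.6% of the control (95% interval 87.5 to 87.7) and 328756 reads or 91.4% of the MC-LR library (91.3 to 91.4). Its only exonic match in GENCODE M21 was in the 3′ UTR (exon 6) of Tmem38b, on chromosome 4 from 53860746 to 53860771 (GRCm38, plus strand). Its CPM ratio was 1.04 (1.04 to 1.05). Set against all other piRNA reads, its level was 7.05 in the control and 10.6 in the MC-LR library, a ratio of 1.5 (1.47 to 1.52). The reads outside it numbered 30307 and 31115, or 12.4% and 8.65% of the libraries, a CPM ratio of 0.696.

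Among the forms measured, the same 5′-shortened form of mmu_piR_000691 led in both libraries. The 23-nt tag GGAATACCGGGTGCTGTAGGCTT made up 74.7% of its control reads (74.6 to 74.9) and 75.5% of its MC-LR reads (75.3 to 75.6). The annotated 26-nt sequence made up 1.08% and 0.926%. Its reads of 23 and 24 nt outnumbered those of 25 and 26 nt 17.4 times in the control and 20.5 times in the MC-LR library. This gave a ratio of 1.18 (1.15 to 1.21). Reads of the shortest length listed, 3 nt under the annotated sequence, made up 77.6% and 78.1% of this fragment's reads. Still shorter forms may therefore be missing.

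**Figure D1:**
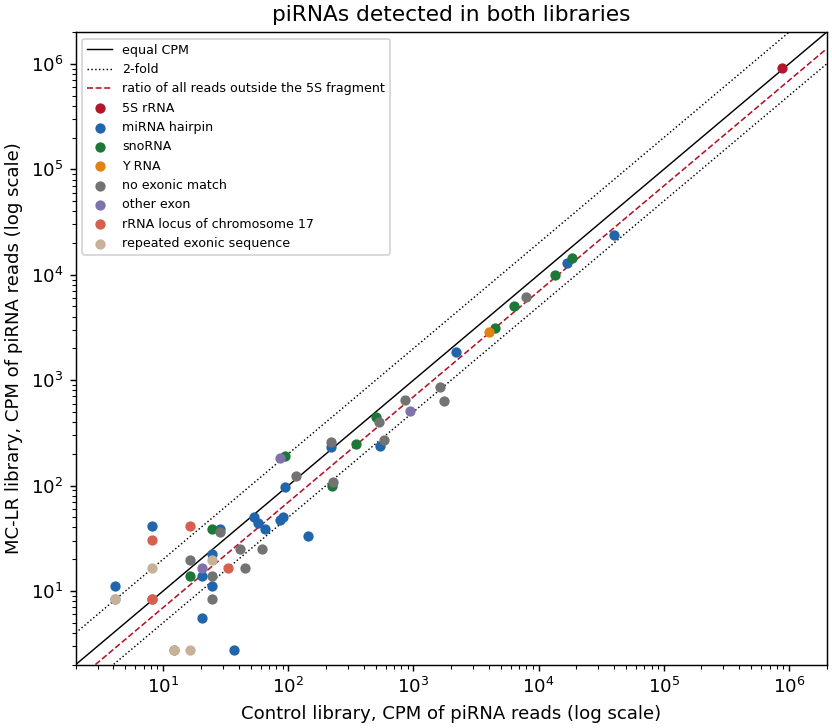
CPM of each of the 63 piRNAs detected in both libraries, control on the x axis and MC-LR on the y axis (both log scales), coloured by the RNA class its sequence matched; the solid line is equal CPM, the dotted lines a fold of 2 and the dashed line the ratio of all reads outside the 5S rRNA fragment, 0.696. The 5S rRNA fragment lies far to the upper right and most abundant piRNAs lie between the solid and the lower dotted line.

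Of the other 9 of the 10 most abundant piRNAs, all but 1 lay within small structural or regulatory RNAs, and that 1 had no exonic match. mmu_piR_025576 (CATGCCTTGAGTGTAGGACCGT), within the Mir532 hairpin on chromosome X (7248456 to 7248477, minus strand), had 9766 control and 8545 MC-LR reads, a CPM ratio of 0.593 (0.576 to 0.611). It was the lowest of the 9, and stayed below 1 at 0.852 (0.828 to 0.877) when scaled to the reads outside the 5S fragment. mmu_piR_017405, within the Mir744 hairpin on chromosome 11 (65734799 to 65734820, minus strand), had 4084 and 4641 reads, a ratio of 0.771 (0.739 to 0.804) that turned to 1.11 (1.06 to 1.15) on that other scale. mmu_piR_028252, within the Mir1839 hairpin on chromosome 7 (81529920 to 81529942, plus strand), had 535 and 672 reads, with ratios of 0.852 (0.759 to 0.956) and 1.22 (1.09 to 1.37).

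Of the 10 most abundant piRNAs, 4 were fragments of small nucleolar RNAs, many of which guide chemical modification of ribosomal RNA. mmu_piR_025007 lies in the snoRNA gene Gm25855 within Snhg1 on chromosome 19 (8724034 to 8724060, plus strand) and had 4544 and 5153 reads, a CPM ratio of 0.769 (0.739 to 0.801). mmu_piR_012107, in Gm24452 of the same host gene (8724574 to 8724600), had 1097 and 1127 reads and a ratio of 0.697 (0.641 to 0.758). mmu_piR_004086 lies in Snord57, in a part of Nop56 that a retained-intron transcript holds as exon, on chromosome 2 (130278016 to 130278044, plus strand). It had 3329 and 3610 reads and a ratio of 0.735 (0.701 to 0.771). mmu_piR_034793, in Gm25789 within Gas5 on chromosome 1 (161038351 to 161038378, plus strand), had 1542 and 1826 reads and a ratio of 0.803 (0.750 to 0.860). Scaled to the reads outside the 5S fragment, these 4 ratios were 1.10, 1.0, 1.06 and 1.15, and the interval included 1 only for mmu_piR_012107 (0.920 to 1.09). The Y RNA fragment mmu_piR_000935, in Rny1 on chromosome 6 (47788151 to 47788180, minus strand), had 978 and 1024 reads, a ratio of 0.710 (0.650 to 0.776) and of 1.02 (0.933 to 1.11) on the other scale. mmu_piR_000580, without an exonic match, had 1925 and 2210 reads and ratios of 0.779 (0.732 to 0.828) and 1.12 (1.05 to 1.19). The 10 most abundant piRNAs together held 99.0% of control reads (98.9 to 99.0) and 99.4% of MC-LR reads (99.3 to 99.4).

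After MC-LR, 3 piRNAs met the rule for higher abundance. mmu_piR_035888, within the Mir3068 hairpin on chromosome 12 (87437686 to 87437705, minus strand), had 2 control and 15 MC-LR reads, a CPM ratio of 5.09 with a wide interval (1.18 to 45.8). mmu_piR_003399 (TGCCAATGATGACACCACACTAACTGAGC) had 21 and 65 reads, a ratio of 2.10 (1.27 to 3.62). It lies in Rpl5, which encodes a protein of the large ribosomal subunit, on chromosome 5 (107904554 to 107904582, plus strand). Only a retained-intron transcript of the gene holds that part as exon. No coding transcript of Rpl5 matched, so it is not placed in the mature mRNA, and the kind of RNA it came from is open. mmu_piR_000705 (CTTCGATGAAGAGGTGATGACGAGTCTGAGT), in Snord15a on chromosome 7 (99482902 to 99482932, minus strand), had 23 and 69 reads, a ratio of 2.03 (1.25 to 3.42). All 3 met the rule under each of the 5 scalings tried, but this was fixed in advance. The scale factor, MC-LR over control, was 1.47 for the total of piRNA reads and 0.920 to 1.13 for the others. Each of the others thus raised every ratio.

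Lower abundance after MC-LR was found for 8 piRNAs. mmu_piR_011141 (TAAGTGCGTGCATGTATATGTGT), within the Mir467c hairpin on chromosome 2 (10473941 to 10473963, plus strand), had 13 reads in the control and 0 in the MC-LR library, at least 6.39-fold lower against the floor of 3 reads. The exact interval of its CPM ratio, which also covers the counting error of the control, reached 0.223. mmu_piR_000273 (AGCTGGTGTTGTGAATCAGGCCGTT), within the Mir138-1 hairpin on chromosome 9 (122682898 to 122682922, plus strand), had 35 and 12 reads, a CPM ratio of 0.233 (0.110 to 0.459). These 2 were lower under each of the 5 scalings. mmu_piR_039147 (CCTCGACACAAGGGTTTGTAA), without an exonic match, had the most reads of the 8, with 432 and 230, and a ratio of 0.361 (0.306 to 0.425). It met the rule under 3 scalings, and its ratio was 0.519 (0.440 to 0.610) against the reads outside the 5S fragment.

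The remaining 5 lower piRNAs met the rule only when scaled to the total of piRNA reads. mmu_piR_020120, within the Mir872 hairpin on chromosome 4 (94665206 to 94665224, plus strand), had 132 and 85 reads and a CPM ratio of 0.437 (0.329 to 0.578). mmu_piR_030130, in Snord17 on chromosome 2 (144265981 to 144266008, minus strand), had 55 and 36 reads and a ratio of 0.444 (0.283 to 0.688). mmu_piR_011982, mmu_piR_027673 and mmu_piR_038322 had no exonic match, and their ratios were 0.407 (0.157 to 0.993), 0.463 (0.354 to 0.604) and 0.472 (0.306 to 0.724). Among piRNAs of up to 22 nt, 4 of 12 tested were lower and 1 was higher, against 4 and 2 of 31 among those from 23 nt. Scaled to the reads outside the 5S fragment, 0 of the 12 and 2 of the 31 were lower, and 1 and 4 were higher, so the balance between the lengths turned with the scaling and was not tested.

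**Figure D2:**
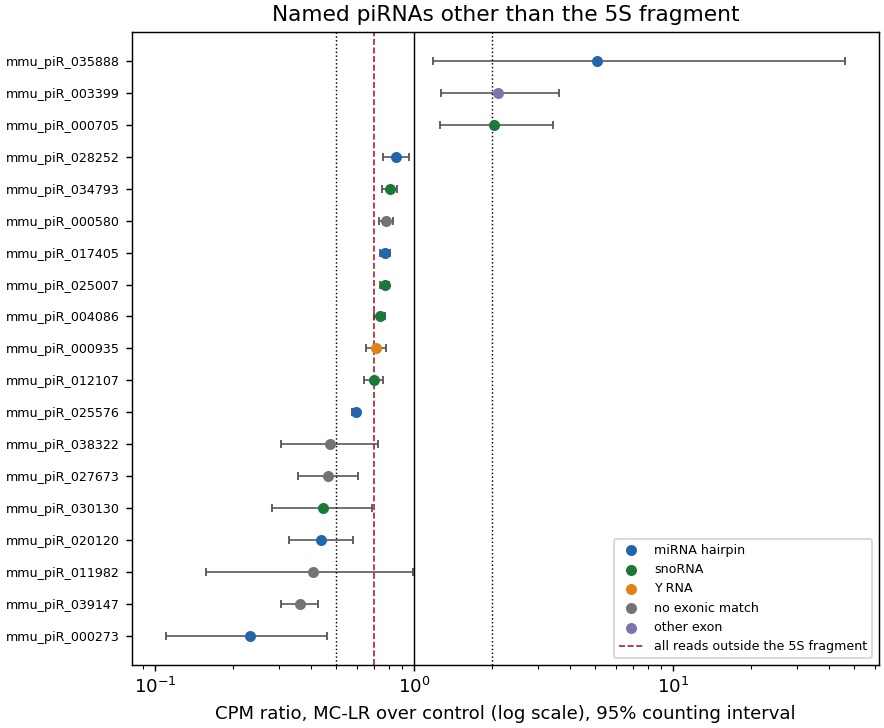
CPM ratio, MC-LR over control (x axis, log scale), of the named piRNAs other than the 5S rRNA fragment and mmu_piR_011141, which had 0 MC-LR reads; points are coloured by RNA class, bars are 95% counting intervals, the solid line is 1, the dotted lines are folds of 2 and the dashed line is 0.696. The 3 higher piRNAs lie to the right at 2.03 to 5.09, the abundant piRNAs lie near the dashed line and the lower ones lie to its left.

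The balance of higher and lower calls depended on the scaling. Scaled to all piRNA reads, 30 of the 42 tested piRNAs other than the 5S fragment lay below a ratio of 1, the median log2 ratio of the 43 tested was -0.40, and 27.3% of the calls were higher. With edgeR TMM factors the median moved by 0.40 to -0.01, with 5 higher and 3 lower piRNAs, 62.5% higher. DESeq2 size factors gave 5 and 3 as well, with a shift of 0.38. Scaled to the total without the 10 most abundant piRNAs the shift was 0.68, and without the 5S fragment alone it was 0.52. Both gave 5 higher and 2 lower, 71.4% higher. The 2 piRNAs added to the higher ones were mmu_piR_000619, with 4 and 15 reads, and mmu_piR_000958, with 2 and 11 reads, named after their values were seen. Both lie in a locus of chromosome 17 annotated as ribosomal RNA, on the strand opposite to that annotation. The strand of the annotation was not checked against a ribosomal RNA sequence, so both may be fragments of the ribosomal RNA strand itself.

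Grouped by the RNA they match, miRNA hairpins and snoRNAs held most reads outside the 5S fragment. The 26 piRNAs within miRNA hairpins made up 48.8% of those reads in the control (48.2 to 49.3) and 45.7% in the MC-LR library (45.1 to 46.2), a ratio of 0.937 (0.915 to 0.959). That ratio rested on mmu_piR_025576: without it the other 25 had 5010 and 5667 reads, a ratio of 1.10 (1.06 to 1.14). The 10 piRNAs within snoRNAs made up 35.7% (35.1 to 36.2) and 38.9% (38.3 to 39.4), a ratio of 1.09 (1.06 to 1.12), close to that of the other hairpins. As shares of all piRNA reads both were lower after MC-LR, with CPM ratios of 0.652 (0.637 to 0.668) and 0.759 (0.739 to 0.779). Of 15 hairpin piRNAs tested, 1 was higher (Mir3068) and 3 were lower (Mir467c, Mir138-1 and Mir872), the last on the scale of all piRNA reads alone. The Mir3068 sequence also matches a snoRNA entry of that name and counts as a hairpin by the order of classes. Of 9 snoRNA piRNAs tested, 1 was higher (Snord15a) and 1 lower (Snord17), with 0 lower against the reads outside the 5S fragment. The 19 piRNAs without an exonic match had a CPM ratio of 0.681 (0.650 to 0.715), with 4 of 13 tested lower, and 0 lower on that other scale. The reference used here lacks the full ribosomal RNA precursor, so this class can include ribosomal RNA fragments. The 6 piRNAs of the ribosomal RNA locus on chromosome 17 had 16 control and 44 MC-LR reads together, a CPM ratio of 1.87 (1.03 to 3.54). By annotation all 6 lie on the strand opposite to the ribosomal RNA entry CT010467.1, and 4 of them match the lincRNA Gm42418 in sense. The strand of that entry was not checked against a ribosomal RNA sequence, so fragments of the ribosomal RNA strand itself are not excluded. 5S rRNA, this locus, miRNA hairpins, snoRNAs, Y RNA, snRNA and tRNA together held 98.5% of control reads (98.4 to 98.5) and 99.0% of MC-LR reads (98.9 to 99.0). The medians of the hairpin, snoRNA and unmatched lists stood at percentiles of 57.7, 64.0 and 12.6 among random lists.

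**Figure D3:**
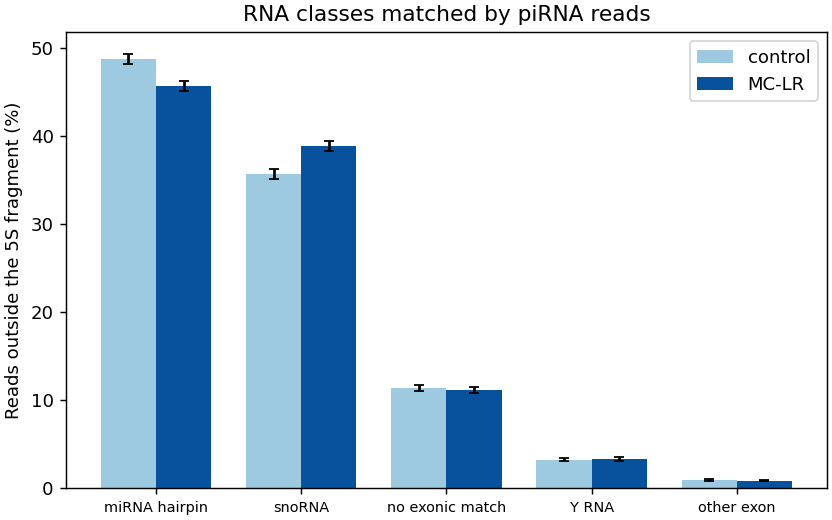
Share of reads outside the 5S rRNA fragment (y axis, percent) by the RNA class that the piRNA sequence matched (x axis), for the control (light) and MC-LR (dark) library; error bars are exact 95% binomial intervals. miRNA hairpins stood at 48.8% and 45.7% and snoRNAs at 35.7% and 38.9%.

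Among the structural RNA fragments fixed beforehand, 5S rRNA and the Y RNA were the only kinds with 10 reads or more. Together the structural sequences held 88.0% of control reads (87.9 to 88.1) and 91.6% of MC-LR reads (91.5 to 91.7), and 2 members were tested with 0 calls. The snRNA list had 3 control reads and 0 MC-LR reads, the tRNA list had 1 and 0, and 7SK had 0 in both, counts too small for a difference to be detectable. The floor of 3 reads stands at 12.3 CPM in the control and 8.34 CPM in the MC-LR library.

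Features of primary and secondary piRNAs were read from the tags. A first-base U, typical of primary piRNAs, was carried by 9.19% of control reads (9.07 to 9.30) and 7.54% of MC-LR reads (7.46 to 7.63), but without the 5S fragment by 38.3% (37.8 to 38.9) and 41.4% (40.8 to 41.9). An A at position 10, typical of piRNAs made by the ping-pong cycle, was carried by 6.08% (5.99 to 6.18) and 3.90% (3.84 to 3.96), and without the 5S fragment by 49.0% (48.4 to 49.6) and 45.1% (44.6 to 45.7). Both of these latter differences rested on mmu_piR_025576 of the Mir532 hairpin. Without it as well, the shares for U were 56.5% (55.8 to 57.2) and 57.1% (56.4 to 57.7). Those for A at position 10 were 24.8% (24.2 to 25.4) and 24.4% (23.84 to 24.96). Both intervals of these differences include 0. Without the 10 most abundant piRNAs, the shares for U were 22.4% (20.8 to 24.1) and 19.5% (17.9 to 21.2). Those for A at position 10 were then 34.5% and 31.1%. Counting each detected piRNA once gave 46.1% and 46.8% for U. The read share of U outside the 5S fragment thus rested largely on the most abundant piRNAs. The annotated length averaged 25.9 nt over the reads of each library (difference 0.056 nt). The read length averaged 23.4 nt, over tags at most 3 nt shorter than their piRNA.

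Of the lists by length and base, piRNAs of 26 to 28 nt had 14 tested members, 0 higher and 1 lower (percentile 53.0 of the median among random lists). Those of 29 to 31 nt had 8 tested, 2 higher (Snord15a and Rpl5 fragments) and 1 lower, at a percentile of 92.1. piRNAs with a first-base U had 1 higher and 2 lower of 13 (44.5), and those without had 2 higher and 6 lower of 30 (70.6). piRNAs with A at position 10 had 2 higher and 2 lower of 10 (64.1). Those with 1 exonic locus had 3 higher and 4 lower of 29 (91.7), and of those with more than 10 loci 1 was tested, with 0 calls. Scaled to the reads outside the 5S fragment, the balance moved towards higher calls: 2 higher and 0 lower for 26 to 28 nt, 2 and 0 for 29 to 31 nt, 4 and 1 without a first-base U, 2 and 0 with A at position 10, and 5 and 2 with 1 exonic locus. With a first-base U it was 1 and 1.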

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

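No paired analysis was possible because each group has 1 library. The rule of size, the rule for naming piRNAs, the lists by structural RNA, length, base and number of loci and most alternatives were fixed before the data were examined; the lists by RNA class, classes without their leading member, scaling without the 5S fragment, bases and lengths of the other sequence (read or annotated piRNA) and shares without the 5S fragment were added afterwards. Of the 84 values of single named piRNAs under other scalings, 22 stayed within their interval or call, 40 moved and 22 no longer met the rule or were weaker. The count of higher piRNAs was 3 and became 5 under TMM, DESeq2 and both reduced totals, and 0 where the interval had to lie wholly beyond a fold of 2. The count of lower piRNAs was 8 and became 3 under TMM and DESeq2, 2 under both reduced totals, 5 with at least 50 reads and 3 with intervals beyond a fold of 2. The scale factor itself moves these counts; the stricter minimum and interval leave fewer piRNAs able to pass. The remaining alternatives gave 2 to 4 higher and 7 to 11 lower.

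Differences, MC-LR minus control, depended on the 5S fragment. The share of the most abundant piRNAs differed by 0.386 points for 10, 0.970 for 5 and 0.045 for 20. Counting each detected piRNA once gave 0.701 points for first-base U, 2.29 for A at position 10, -0.035 nt for length, -1.37 points for structural RNA and -3.33 for ribosomal RNA and the small RNA classes together, all reversed and all with intervals that include 0. Without the 10 most abundant piRNAs the values were -2.87, -3.42, 0.686, -0.116 (reversed) and 5.18, in the same order. Without the 5S fragment they were 3.08 (reversed), -3.88, 0.257, 0.054 and 0.248. The ratio of miRNA hairpin reads among reads outside the 5S fragment, 0.937, turned to 1.10 (reversed) without mmu_piR_025576, and that of snoRNA reads was 1.09 and 1.08 without mmu_piR_025007. Without mmu_piR_025576 as well, added afterwards too, they were 0.540 (reversed), -0.389, 0.054, -0.239 (reversed) and 1.53; the first 4 have intervals that include 0. Length of the read in place of the piRNA gave -0.023 nt, reversed. Beyond the removal of the sequences named, the cause was not tested. Depth limits piRNAs with few reads most: 26 of the 27 seen in 1 library alone had fewer than 10.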

Other observations

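All tests in this part were chosen after the results were seen. Outside the comparisons above, a pair of piRNAs from 1 hairpin changed in their ratio. mmu_piR_025576 and mmu_piR_028975 (CCTCCCACACCCAAGGCTTGCA) both lie within the Mir532 hairpin transcript on chromosome X, the latter from 7248419 to 7248440. Their reads were 9766 and 54 in the control and 8545 and 84 in the MC-LR library, so that the ratio of the first to the second was 181 and then 102, a ratio of ratios of 0.562 (0.399 to 0.793). This comparison within a library needs no scaling. The CPM ratio of the second alone was 1.05 (0.741 to 1.51), and 1.52 (1.06 to 2.17) when scaled to the reads outside the 5S fragment. How far each of the 2 moved therefore depends on the scaling. The Snord15a and Rpl5 fragments, measured against the other reads outside the 5S fragment, stood 2.97 times as high in the MC-LR library (2.12 to 4.18), from 44 and 134 reads; both were picked as higher from these same counts.

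The 5S rRNA fragment stood 1.5 times as high against all other piRNA reads after MC-LR, while reads outside it were nearly equal in number. A difference in size selection would raise other reads of the same lengths. Reads of 23 and 24 nt from other piRNAs had a ratio of ratios of 1.09 (0.911 to 1.30), short of 1.5. Of these 233 control and 260 MC-LR reads, 143 and 155 were 1 tag of mmu_piR_028252, so the comparison rests largely on 1 RNA. Within the 5S fragment, reads of 23 and 24 nt against those of 25 and 26 nt had a ratio of ratios of 1.18 (1.15 to 1.21). A difference by length is thus not excluded. A higher share of ribosomal RNA fragments of several kinds in the MC-LR library stays open. The 6 piRNAs of the chromosome 17 locus stood 2.68 times as high against the other reads outside the 5S fragment (1.51 to 4.75), from 16 and 44 reads. Whether they come from the ribosomal RNA strand was not checked. Without mmu_piR_000619 and mmu_piR_000958, already picked as higher from these counts, the other 4 had 10 and 18 reads, a ratio of 1.75 with an interval that includes 1 (0.810 to 3.80). The 19 piRNAs without an exonic match, which can include ribosomal RNA fragments, were counted among the other reads in these comparisons. They had 3439 and 3455 reads, a ratio of 0.979 (0.933 to 1.03) when scaled to the reads outside the 5S fragment. Which of them are ribosomal was not determined, so the chromosome 17 locus cannot stand for all such fragments. The toxin and library preparation cannot be told apart, with 1 library per group.

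Short reads were scarcer in the MC-LR library. Outside the 5S fragment, the CPM ratio was 0.392 at 18 nt (0.325 to 0.471) and 0.455 at 19 nt (0.40 to 0.517), against 0.761 at 27 nt (0.737 to 0.785), and reads of 18 and 19 nt against longer ones gave 0.615 (0.554 to 0.683). If the library took up fewer of the shortest reads whatever their RNA, the same drop would be seen within each piRNA. Within the 8 piRNAs with reads of both kinds the pooled (Mantel-Haenszel) ratio was 0.862 (0.708 to 1.05), from 358 of the 922 short control reads, all of 19 nt. Its interval excludes 0.615 but includes 1, and 0.615 covers all piRNAs outside the 5S fragment and not these 8. The members also moved apart. For mmu_piR_020692 short and longer reads went from 133 and 95 to 122 and 61. For mmu_piR_027673 they went from 73 and 69 to 42 and 55. The pooled ratio therefore does not decide the question. The other 564 short control reads came from mmu_piR_039147 (432, with every 18-nt control read) and mmu_piR_020120 (132), both among the lower piRNAs. Neither has reads of 20 nt or more, and mmu_piR_020120, annotated at 19 nt, could not, since longer forms were not measured. Within mmu_piR_039147 reads of 18 nt went from 317 to 182 and reads of 19 nt from 115 to 48, a ratio of ratios of 1.38 (0.938 to 2.02), with no sign of a greater loss at 18 nt. For these 2 RNAs a loss of 18-nt and 19-nt reads alike and a fall of the RNAs cannot be told apart, and a difference between the cells stays open and untested.

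The numbers of the tags carry information on the reads outside the piRNA tables. A candidate explanation is that tags were numbered over both libraries by falling larger read count: 0 of 41616 pairs of the 289 tags were out of that order, against 961 if ordered by the sum of both counts. On that reading the leading 5S tag, number 12 with 248065 MC-LR reads, was preceded by 11 tags with at least as many reads in a library that match no piRNA, and numbers reach 429885. The reads of both libraries would then total at least 7885988, of which the 603937 piRNA reads make up at most 7.66%.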
